A study of Mus musculus with 2 samples.

How the data were processed

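The 2 total RNA libraries of adrenal gland of male B6Cast F1 mice at postnatal day 10 were analysed, 1 per replicate, as a single group. Replicate numbers are those of the labels. The characteristics give the animals the numbers 3 and 4, while both library descriptions carry the animal number 3, so the animal of replicate 2 is stated in conflicting ways. Both samples carry the same donor identifier, and the tables cannot show whether they come from different animals.

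Per the file headers and the notes deposited with them, the authors derived a gene table and a transcript table from alignments to the transcriptome (mm10, GENCODE release M21 with tRNA genes, ERCC spike-ins and phiX). Their column names are those of RSEM, and they hold expected counts per gene, not normalised, and TPM over all entries, spike-ins included. The deposited second transcript table was derived directly from the reads and an index and has the column names of kallisto, with estimated counts and TPM. The aligner, the tools and their versions are not given in the sources used here. The deposited interval bounds of TPM were not used here. The gene tables list 81881 entries, of which 55536 are annotated genes, 26248 tRNAs, 96 spike-ins and 1 phiX. Gene identifiers were matched to the GENCODE M21 annotation for symbol, biotype and coordinates. The symbol Ahsp of the erythroid list was not matched.

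Expected counts totalled 36982665 and 38984236 over all entries, 36652695 and 38641442 of them on annotated genes. Ratios of replicate 2 over replicate 1 used expected counts scaled by TMM (edgeR 4.0.16), with a prior of 0.5 counts on the log2 scale, and fold values of single genes used the scaled counts without a prior. Members with 3 or fewer counts in both libraries were left out of list ratios. Fold intervals are exact binomial (Clopper-Pearson) 95% intervals, and a count of 0 was read as a floor of 3 counts per library. All intervals and floors cover counting error only, since reads carry no molecular identifiers. The scaling factors of the alternatives differed from TMM by less than 0.1 on the log2 scale.

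Detected genes had at least 1 TPM in both libraries. Correlations used log2(TPM + 1) across genes. The count of genes more than 2-fold apart used genes with a mean of at least 100 expected counts. The biological coefficient of variation is the square root of the edgeR common dispersion of rounded counts with an intercept only after its default expression filter. The chi-square index used genes with a mean of at least 10 counts.

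A set of 37 lists, 21 of cell type markers and 16 of gene groups, was fixed. The level of a list is the median of log2(TPM + 0.1). The median log2 ratio of a list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list stood apart when it lay outside the middle 95%. Follow-up lists were written later, each before the values of its members were looked up: a second liver list, a second skeletal muscle list, a second zona glomerulosa list, a second brown fat list, a second bone and cartilage list and a PPARA target list.

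Genes were named by a fixed rule: the 4 most abundant members of each list, all members of steroid synthesis, catecholamine synthesis and handling, the adrenal zones, Y-linked and X inactivation, the 10 most abundant nuclear protein-coding genes and the 5 of other biotypes, the 10 highest and 10 lowest replicate ratios, the 5 highest and 5 lowest ratios between the 2 quantifications, and the main transcript of each synthesis gene with 2 or more transcripts and at least 10 TPM. Members outside the rule that are given as examples of a list (among them Gli1, Pdgfra, Cnn1, Pdgfrb, Mpo, Cd8a, Cd14, Lep, Fosb, Fkbp5, Mki67 and Umod) were chosen after their values were seen. Values of certain single genes that the rule takes are not reported here.

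The main computations were tested on simulated data with a known answer. Lists of 10 genes with no shift stood apart in 7% of simulations, and with a log2 shift of 0.5 in 90.5%. Coefficients of variation of 0.05, 0.15 and 0.3 were estimated as 0.0492, 0.151 and 0.294. Genes set 4-fold apart passed the 2-fold threshold in 99% of cases, and 1.56% of genes with no difference did.

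Alternatives covered scaling by DESeq2 (1.42.0) size factors, by library total and by spike-in total, other pseudocounts, thresholds and count minimums, the mean in place of the median of a list, TPM rescaled over nuclear protein-coding genes, the second transcript table, and each library alone where a value exists for one. Computations ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Allele-specific expression was not analysed here, since the tables hold no counts per allele.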

Results

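Total RNA was sequenced from 2 samples of adrenal gland of male mice at postnatal day 10. The mice were B6Cast F1 hybrids, the first-generation cross of C57BL/6J and CAST/EiJ, and each sample gave 1 library from 300 ng of RNA with ERCC spike-ins, synthetic transcripts of known amount. The libraries form a single group of 2 biological replicates, so no condition was compared with another. The deposited gene tables held 36982665 expected counts for replicate 1 and 38984236 for replicate 2. The comparisons below describe what the tissue expressed and how far the 2 replicates lay apart. The labels call them biological replicates and number the animals 3 and 4, but give both the same donor identifier, so a difference between them cannot be assigned to a difference between animals. With 1 library per replicate no gene has a p-value, and the smallest two-sided exact p that 2 libraries allow is 0.5. The labels and the series record state no purpose beyond profiling this tissue.

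Both libraries carried the transcripts of a steroid-producing cortex and of a catecholamine-producing medulla at high level. Star, which delivers cholesterol to the inner mitochondrial membrane, stood at 1535 ± 107 TPM (SD, n = 2), and Hsd3b1, which makes progesterone from pregnenolone, stood at 1692 ± 228 TPM (SD, n = 2). Th, the rate-limiting enzyme of catecholamine synthesis, stood at 162 ± 12.6 TPM (SD, n = 2), and Pnmt, which makes adrenaline from noradrenaline, at 286 ± 19.1 TPM (SD, n = 2). The median of the 12 cortex markers exceeded the median of the 18 chromaffin markers by 3.65 ± 0.04 on the log2 scale (SD, n = 2), a ratio of 12.5. This was 3.62 in replicate 1 and 3.68 in replicate 2. The value depends on taking the median over genes, since the means of the lists differed by 2.83.

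The genes of glucocorticoid and mineralocorticoid synthesis were expressed together, with the last enzyme of the glucocorticoid branch far above that of the aldosterone branch. Cyp21a1, the steroid 21-hydroxylase, was at 903 ± 62.2 TPM (SD, n = 2), Cyp11a1, the side-chain cleavage enzyme, at 664 ± 59.3 TPM (SD, n = 2), and Fdx1, its electron donor, at 603 ± 67.6 TPM (SD, n = 2). Cyp11b1, the 11-beta-hydroxylase of the zona fasciculata, was at 551 ± 65.1 TPM (SD, n = 2), and Cyp11b2, the aldosterone synthase of the zona glomerulosa, at 55.5 ± 23.8 TPM (SD, n = 2). Cyp11b1 exceeded Cyp11b2 by 3.04 on the log2 scale in replicate 1 and by 3.70 in replicate 2, with a mean of 3.37 ± 0.47 (SD, n = 2). These paralogs lie side by side on chromosome 15 in mm10, Cyp11b1 (ENSMUSG00000075604.5) at 74834125 to 74841643 and Cyp11b2 (ENSMUSG00000022589.7) at 74851010 to 74856318, and some of their reads can be assigned to either. Star (ENSMUSG00000031574.8) lies on chromosome 8 at 25806555 to 25815982.

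Cyp17a1, the 17-alpha-hydroxylase that mice need for sex steroids and not for corticosterone, was at 3.88 ± 0.96 TPM (SD, n = 2). Among isoenzymes, Hsd3b1 exceeded the zona glomerulosa form Hsd3b6 by 6.75 ± 0.14 on the log2 scale (SD, n = 2). The zona fasciculata markers had a median of 118 ± 13.6 TPM (SD, n = 2), led by Cyp11b1 and by Akr1b7, an aldo-keto reductase, at 514 ± 82.3 TPM. The zona glomerulosa markers had a median of 11.8 ± 2.46 TPM (SD, n = 2), with Dab2 the highest at 121 ± 28.5 TPM. Of the X-zone markers, Akr1c18, which inactivates progesterone, was at 121 ± 8.35 TPM, Cyp2f2 at 98.3 ± 2.22 TPM, Thrb at 10.4 ± 1.09 TPM and Pik3c2g at 1.10 ± 0.69 TPM (SD, n = 2). The remaining members of steroid synthesis were Fdxr at 138 TPM, Tspo at 99.5 TPM, Por at 71.9 TPM, Hsd11b1 at 25.5 TPM, Srd5a1 at 4.16 TPM and Hsd11b2 at 0.520 TPM (means, n = 2). The uptake receptor Scarb1 was at 433 ± 29.5 TPM (SD, n = 2), while the 21 genes of cholesterol synthesis and uptake had a median of 13.8 ± 1.51 TPM (SD, n = 2).

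Within each library, Pnmt exceeded Th by 0.82 ± 0.02 on the log2 scale (SD, n = 2), and Star exceeded Th by 3.25 ± 0.01 (SD, n = 2). The samples are labelled adrenal gland and not medulla, so the values below are not those of the medulla alone. Th (ENSMUSG00000000214.11) lies on chromosome 7 at 142892752 to 142931128 and Pnmt (ENSMUSG00000038216.7) on chromosome 11 at 98386450 to 98388181. Dbh, which makes noradrenaline, was at 120 ± 15.6 TPM and Ddc, the decarboxylase before it, at 25.4 ± 1.83 TPM (SD, n = 2). The granule proteins Chga and Chgb were at 428 ± 69.6 and 365 ± 58.2 TPM, and the peptide precursor Npy was at 191 ± 11.3 TPM (SD, n = 2). The vesicular transporters Slc18a1 and Slc18a2 were at 6.94 ± 1.34 and 6.20 ± 0.66 TPM, the noradrenaline transporter Slc6a2 was at 6.48 ± 2.38 TPM, and Gch1, for the cofactor of Th, was at 12.6 ± 1.15 TPM (SD, n = 2). The degrading enzymes Maob and Maoa were at 8.91 ± 3.21 and 6.97 ± 0.82 TPM (SD, n = 2).

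**Figure D1:**
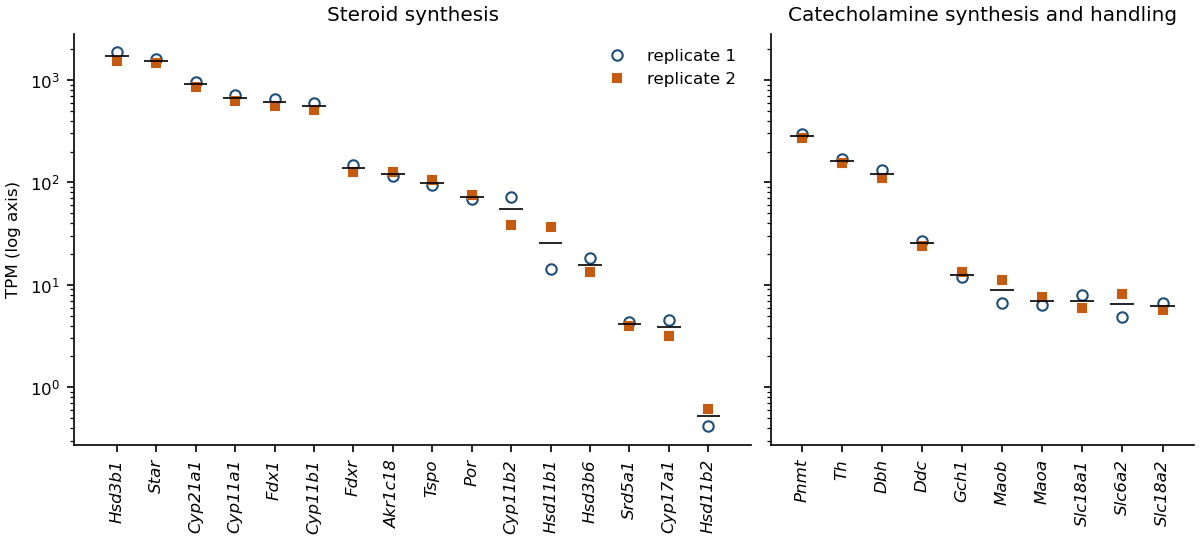
TPM on a log axis for genes of steroid synthesis and of catecholamine synthesis and handling, with an open circle for replicate 1, a filled square for replicate 2 and a line at their mean. Hsd3b1 and Star lie above 1000 TPM in both libraries, and Hsd11b1 and Cyp11b2 show the wide gaps between the replicates.

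Markers of tissues outside the gland were also abundant in both libraries. The 7 brown adipocyte markers had a median of 437 ± 4.04 TPM (SD, n = 2), with Ucp1, the uncoupling protein of brown fat, at 1357 ± 295 TPM, Cox8b at 937 ± 18.2 TPM and Cox7a1 at 496 ± 8.32 TPM. The 9 adipocyte markers had a median of 119 ± 13.3 TPM, led by Fabp4 at 1805 ± 2.98 TPM. The 8 liver markers had a median of 182 TPM in replicate 1 and 529 TPM in replicate 2. The 7 skeletal muscle markers had a median of 35.0 TPM in replicate 1 and 90.4 TPM in replicate 2. By contrast, none of the 10 kidney markers and none of the 6 pancreas markers reached 1 TPM in both libraries, and their medians were 0.0025 and 0.030 TPM. The kidney marker Umod had 0 counts in both libraries, which allows up to 3 counts in each.

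Among other cell types, the endothelium list had a median of 30.4 ± 2.31 TPM, with Egfl7 at 69.7 TPM and Cdh5 at 53.0 TPM. The erythroid list had a median of 13.9 ± 2.03 TPM, with Hba-a1 at 1241 ± 56.1 TPM and Hbb-bs at 1177 ± 1.21 TPM, globin copies whose reads are partly shared. Mesothelium markers had a median of 3.71 ± 0.52 TPM. The 4 Y-linked genes had a median of 17.9 ± 1.51 TPM, with Ddx3y at 27.2, Eif2s3y at 26.1, Uty at 9.78 and Kdm5d at 5.19 TPM. Xist was at 0.060 TPM in replicate 1 and 0.010 TPM in replicate 2, Tsix had 2 counts in each library, and the pair of X inactivation genes had a median of 0.025 TPM.

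In all, 13635 genes reached 1 TPM in both libraries, of which 12500 were protein-coding, 460 processed pseudogenes and 127 lincRNAs. The 10 nuclear protein-coding genes with the highest mean TPM were Alb, Eef1a1, Gnas, Fabp4, Hsd3b1, Atp5b, Ahsg, Star, Trf and Ucp1. Of these, Hsd3b1 and Star are cortex enzymes or carriers, Fabp4 and Ucp1 are fat genes, and Alb, Ahsg and Trf encode plasma proteins of the liver. The ranks rest on the mean of both libraries. In replicate 1 Alb, at 2046 TPM, lay below Eef1a1 at 2153 TPM, and Ahsg, at 720 TPM, lay below Hba-a1 at 1201 TPM. Nuclear protein-coding genes took 61.1% ± 0.11 of the expected counts (SD, n = 2) and the mitochondrial genome took 23.1% ± 1.14 (SD, n = 2). The mitochondrial rRNAs alone took 16.8% in replicate 1 and 18.4% in replicate 2. The 5 most abundant nuclear genes of other biotypes were Rn7s1, Rn7s2, Rn7sk, Gm28661 and Gm26917. Rn7s1 and Rn7s2, copies of the signal recognition particle RNA, had equal values at 122164 TPM each, and Gm28661 is a nuclear copy of mitochondrial sequence whose reads are shared with the mitochondrial genome. The misc_RNA class, which holds Rn7s1, Rn7s2 and Rn7sk, took 5.71% ± 0.48 of the counts and 28.6% ± 1.70 of the TPM (SD, n = 2). Spike-ins took 0.892% of the counts in replicate 1 and 0.879% in replicate 2. Of the 96 spike-ins, 75 were above 0 in replicate 1 and 76 in replicate 2. Across all 96, those at 0 included, log2(TPM + 1) correlated at r = 0.999.

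The 2 replicates were close for most genes. Across 55536 genes, which are not independent replicates, log2(TPM + 1) of the libraries correlated with a Pearson r of 0.992 and a Spearman rho of 0.935. Among 13188 genes with a mean of at least 100 expected counts, the median absolute log2 ratio was 0.13, or 1.09-fold, and 591 genes (4.48%) lay more than 2-fold apart. Of these, 576 were higher in replicate 2 and 15 were higher in replicate 1. The biological coefficient of variation, the spread between the replicates beyond counting noise, was 19.5% over 17462 genes. The chi-square index of the counts was 58.2 per degree of freedom over 18175 genes, where simulated sampling noise alone gave 0.990, so the files are not the same library deposited again. With mean counts of at least 10 the number of genes more than 2-fold apart was 1405, and with at least 1000 it was 145.

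Of 35 fixed lists with a value, 18 had a median ratio outside the middle 95% of random lists matched on expression, 13 of them higher and 5 lower in replicate 2, where a share of 5% gives 1.75. In simulated libraries 7% of lists with no shift stood apart. Lists share members and genes of a cell type vary together, so these calls are not independent. All 8 liver markers were higher in replicate 2, 7 of them more than 2-fold, with a median ratio of 3.21. Alb (ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602), the plasma albumin, was 3.06-fold higher (counting interval 3.05 to 3.08), and Apoa1, an apolipoprotein, was 3.46-fold higher (3.40 to 3.52). All 7 skeletal muscle markers were higher, with a median ratio of 2.56, among them Acta1, skeletal actin, at 2.90-fold (2.81 to 3.00). These intervals are exact binomial 95% intervals and cover counting error only, not the difference between samples.

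Immune cell markers followed the same direction. The erythroid list, with a median ratio of 1.13 and Hbb-bs at 1.01-fold, did not stand apart. All 8 granulocyte markers were more than 2-fold higher in replicate 2, with a median ratio of 3.41, among them S100a9 at 3.29-fold and Mpo, the granule peroxidase, at 6.64-fold. Of the 9 lymphocyte markers, 8 were higher, with a median ratio of 2.45, and Cd8a was lower at 0.680-fold. Of the 10 macrophage markers, 9 were higher, with a median ratio of 1.64, and Cd14 was lower at 0.749-fold. The lymphocyte list was near 1 TPM, with a median of 1.06 TPM. All 8 markers of pericytes and smooth muscle were higher, with a median ratio of 2.02, from Pdgfrb at 1.09-fold to Cnn1 at 7.91-fold. The capsule and fibroblast list had a median ratio of 1.30 with Col1a1 at 2.54-fold, while Gli1 was at 1.01-fold and Pdgfra at 0.981-fold. This call was lost when the mean of the list was used, at percentile 96.6. Sympathetic neuron markers had a median ratio of 1.90, with Prph at 3.11-fold, and Schwann and sustentacular markers had a median ratio of 1.38. The adipocyte list had a median ratio of 1.12, with Lep, the hormone leptin, at 4.73-fold and Plin1 at 0.980-fold.

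The 5 lists that stood apart as lower in replicate 2 were zona glomerulosa, cortex, chromaffin cells, steroid synthesis and proliferation, by smaller amounts. All 10 zona glomerulosa markers were lower, with a median log2 ratio of -0.46, or 0.729-fold. Cyp11b2 was at 72.4 TPM in replicate 1 and 38.7 TPM in replicate 2, 0.543-fold (0.515 to 0.572). Vsnl1 was at 0.617-fold, Kcnk9 at 0.627-fold, Agtr1b at 0.644-fold, Shh at 0.703-fold, Dab2 at 0.756-fold, Hsd3b6 at 0.758-fold, Wnt4 at 0.883-fold, Rgs4 at 0.904-fold and Lef1 at 0.969-fold. All 12 cortex markers were lower with a median log2 ratio of -0.14, and 17 of 18 chromaffin markers were lower with a median of -0.13, the exception being Slc6a2 at 1.73-fold. The 16 genes of steroid synthesis had a median log2 ratio of -0.14, while Hsd11b1, which reactivates glucocorticoids, was 2.59-fold higher. This call was lost with the mean of the list, at percentile 15.4. All 16 proliferation genes were lower with a median log2 ratio of -0.19, among them Mki67 at 0.766-fold and Top2a at 0.818-fold. Every difference in this paragraph is within 2-fold except that of Hsd11b1.

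Immediate early genes were higher in replicate 2 in all 10 members, with a median ratio of 1.49, among them Nr4a1 at 1.78-fold, Egr1 at 1.60-fold and Fosb at 4.77-fold. The glucocorticoid responsive list had a median ratio of 1.25, with Ddit4 at 1.47-fold, Per1 at 1.42-fold and Fkbp5 at 0.960-fold. With the mean of the list this call was lost, at percentile 97.0. The mitochondrial genome list had a median log2 ratio of 0.08 under TMM scaling, which turned to -0.00170 under the library total, and its call was lost with the mean of the list and in the second transcript table.

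The other lists lay inside the middle 95%. Median log2 ratios of replicate 2 over replicate 1 were -0.15 for zona fasciculata, 0.25 for the X-zone, -0.0013 for endothelium, 0.18 for erythroid cells, -0.01 for brown adipocytes, 0.31 for mesothelium and -0.29 for the 3 kidney markers with enough counts. They were -0.03 for cholesterol synthesis and uptake, -0.11 for catecholamine synthesis and handling, 0.17 for heat shock, 0.04 for the circadian clock, -0.07 for imprinted genes and 0.06 for the nuclear respiratory chain. They were -0.12 for replication-dependent histones, -0.16 for abundant noncoding RNA, -0.01 for ribosomal proteins and -0.12 for Y-linked genes. Within brown adipocytes Ucp1 was at 0.745-fold and Cidea at 1.03-fold, and this list and zona fasciculata stood apart as lower in replicate 2 when the mean was used. A second brown fat list stood apart as higher, at percentile 99.98, with 6 genes higher and 4 lower. Erythroid cells stood apart in the second transcript table, at percentile 98.0. With members of at least 100 counts, catecholamine synthesis and handling, heat shock and abundant noncoding RNA stood apart, at percentiles 2.10, 97.7 and 1.90. Pancreas and X inactivation had 1 member each with enough counts and no value.

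**Figure D2:**
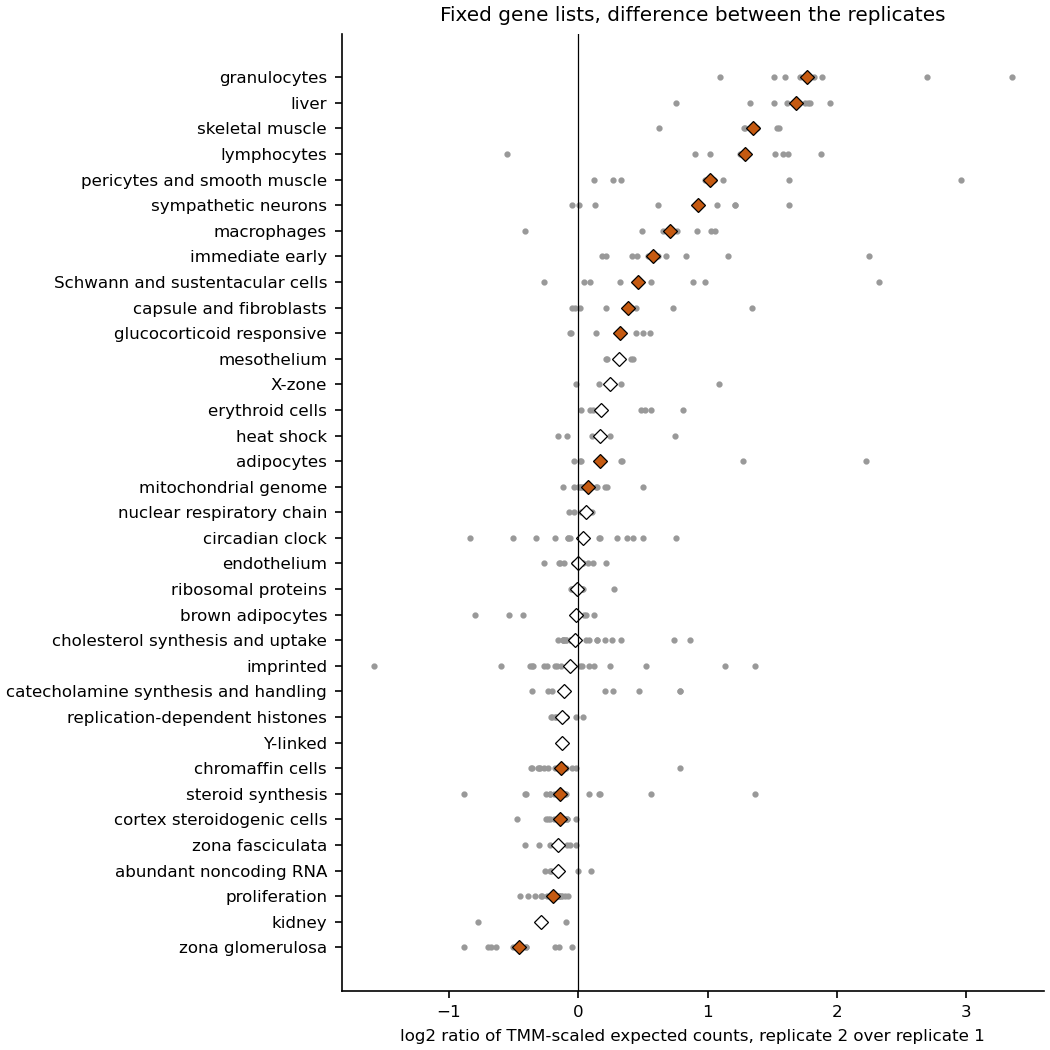
Log2 ratios of replicate 2 over replicate 1, after TMM scaling, for the fixed lists, with a grey dot per gene and a diamond at each list's median, filled where the median lay outside the middle 95% of matched random lists. Granulocytes, liver and skeletal muscle lie farthest to the right, and zona glomerulosa lies farthest to the left.

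Several genes of bone and cartilage were nearly absent in replicate 1 and present in replicate 2. Among protein-coding genes with a mean of at least 100 counts, the 10 highest ratios belonged to Ibsp, Mmp13, Dmp1, Col2a1, Fgf21, Tnn, Bglap, Inhbe, Mmp9 and Cyp4a10. Ibsp, the bone sialoprotein, had 1 count in replicate 1 and 394 in replicate 2, a ratio of 395 (70.4 to 15626). Mmp13, a collagenase of growing bone, had 3 and 393 counts, a ratio of 131 (44.6 to 639), and Dmp1, an osteocyte protein, had 2 and 281, a ratio of 141 (38.6 to 1168). Col2a1, the collagen of cartilage, was 56.5-fold higher (35.6 to 95.7) and Bglap, osteocalcin, was 29.7-fold higher (17.5 to 52.5). Fgf21, a hormone the liver secretes, had 6 and 230 counts, and Cyp4a10, a fatty acid hydroxylase, was 18.4-fold higher (12.2 to 28.5).

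The 10 lowest ratios were those of Hist1h2ao, Gm45837, 1700047I17Rik2, Tchh, Gm14440, Rag1, Dhrs9, Grm4, Gmpr and Slc15a2. Gmpr, a GMP reductase, was at 193 TPM in replicate 1 and 76.5 TPM in replicate 2, 0.396-fold (0.382 to 0.411). Dhrs9, a retinol dehydrogenase, was at 0.362-fold (0.321 to 0.408), Rag1, the recombinase of lymphocytes, at 0.249-fold (0.178 to 0.343) and Tchh, the hair protein trichohyalin, at 0.0866-fold (0.0485 to 0.144). Hist1h2ao, of a histone family with near-identical copies, had 710 expected counts in replicate 1 and 0 in replicate 2 of the gene table. In the second transcript table it stood at 1.63 TPM in replicate 1 against 50.9 TPM in the gene table and was listed at 0 in replicate 2, so the size of its difference depends on the table. Gm45837, at 223 and 0.320 expected counts, had a log2 ratio of 0.07 in the second transcript table. Gm14440 had 239 and 28.9 expected counts but 1.99 and 1.66 TPM in replicates 1 and 2 of the gene table. The second transcript table held 0 and 0.00024 TPM for Gm14440. For 1700047I17Rik2, at 389 and 1.11 expected counts, it held 3.6e-05 and 0.00084 TPM.

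Each library also has a second table of transcript abundances made directly from the reads. Summed per gene, log2(TPM + 1) of the 2 tables correlated across genes at a mean Pearson r of 0.947 ± 0.0021 (SD, n = 2) and per transcript at 0.779 ± 0.0021 (SD, n = 2). The Spearman values were 0.890 and 0.729. Among genes with at least 1 TPM in either table, 3440 in replicate 1 and 2790 in replicate 2 lay more than 2-fold apart, a mean of 3115, and at a minimum of 10 TPM the mean was 1583. At that minimum the second table was higher in a mean of 1293 genes and lower in 290, but after rescaling over nuclear protein-coding genes the mean was 700.5, with 190 higher and 510.5 lower, so the direction depends on the scale. The lowest ratios of the second table to the first among coding genes of at least 10 TPM were those of mt-Atp8 at -15.82, Hist2h2aa2 at -11.66, Rpl10-ps3 at -11.57, Rpl9-ps6 at -8.86 and Gm11808 at -8.62 on the log2 scale. The highest were those of Hist2h2aa1 at 5.91, Atp5g2 at 4.87, Hist1h2ad at 4.75, Cycs at 4.07 and Rpl27 at 3.73. Several belong to families with near-identical copies, such as histones and ribosomal proteins. Detected coding genes were higher in the second table by a median of 0.63 on the log2 scale, and misc_RNA took 0.000369% of its counts.

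Of 17 genes of steroid and catecholamine synthesis with several annotated transcripts, 13 had the same most abundant transcript in both tables. In the first table a single transcript held over 90% of the gene's TPM in 9 of the 17. Shares given without a table are those of the first. Th-201 held 99.95% ± 0.070 in the first table but 76.1% ± 3.21 in the second (SD, n = 2). Pnmt-201 held 99.9% ± 0.0094 and Dbh-201 held 99.7% ± 0.41, while Star-202 held 50.3% ± 0.17 (SD, n = 2). The tables named different transcripts for Tspo, Hsd3b1, Hsd11b1 and Ddc. Tspo-201 held 98.7% in the first table and 45.3% in the second, Hsd3b1-201 held 64.8% and 38.2%, Hsd11b1-205 held 74.8% and 4.24%, and Ddc-202 held 52.4% and 1.3e-08%. Among the other genes the top transcript was Cyp11a1-201 at 98.4%, Gch1-201 at 96.5%, Fdx1-201 at 95.9%, Cyp21a1-201 at 95.6%, Fdxr-201 at 93.4%, Por-201 at 89.2%, Akr1c18-201 at 88.9% and Hsd3b6-201 at 75.2% of the gene's TPM.

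**Figure D3:**
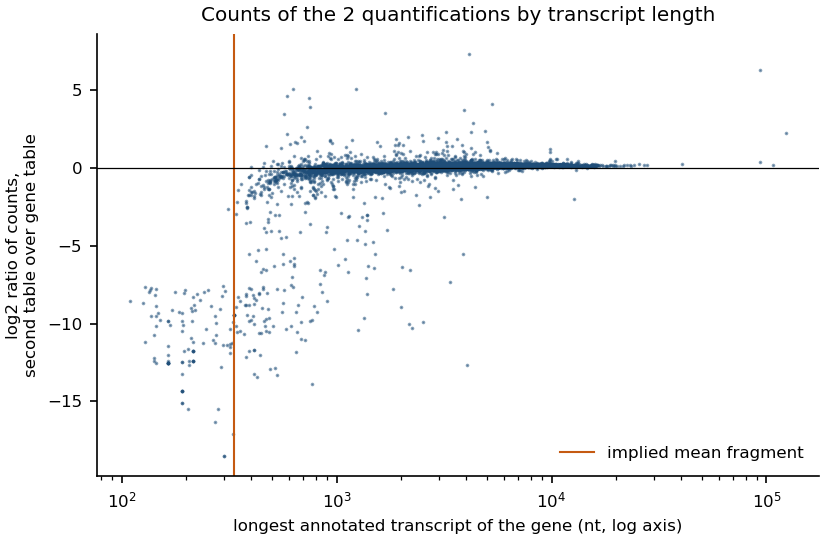
Log2 ratio of the counts of the second table to those of the gene table against the length in nucleotides, on a log axis, of each gene's longest annotated transcript, with a dot per gene and a vertical line at the mean fragment of 332 implied by the second table. The 102 genes shorter than that line have a median of -11.12, and the 12959 genes longer than 1.5 times the line have a median of 0.11.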

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

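The comparison of the liver list with all genes, the random lists drawn for the zona glomerulosa and the comparison with the capsule and fibroblast list were chosen only after the results were seen, as was the requirement that a follow-up zone list or the capsule list clear its limit by more than the spread of its members. The tRNA entries, which no comparison uses, held 4 expected counts in replicate 1 and 5.81 in replicate 2, summed over 26248 entries.

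Transcripts of liver and of other tissues were higher in replicate 2. A factor for a whole library moves all genes alike, so scaling or depth is argued against by the median log2 ratio of the liver list minus that of all genes with a mean of at least 100 counts, 1.69 with a member SD of 0.38, and a difference of a few liver genes is argued against by a second liver list of 16 genes, of which 93.75% lay above a log2 ratio of 0.5. That second list shares no gene with the first, had a median log2 ratio of 1.69 with 16 of 16 genes higher, and includes Trf, whose level was already listed among the 10 most abundant coding genes. More liver RNA in the sample of replicate 2 may therefore account for the liver part, with Alb at 2046 and 6173 TPM and Ahsg at 720 and 2421 TPM in replicates 1 and 2, although all 8 genes of the first list are above 1 TPM in both libraries and the tables do not show which cells made them. How such RNA came into the sample was not tested. With 1 group no biological explanation was tested for this pattern, apart from the PPARA hypothesis given under the other observations.

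All 10 zona glomerulosa markers were lower in replicate 2, with a median log2 ratio of -0.46. Dilution of adrenal RNA by other tissue lowers all adrenal markers alike. The zone median lay at percentile 0 of random lists from 44 other cortex and chromaffin markers, whose middle 95% ran from -0.24 to -0.04, and without Cyp11b2 the median was -0.40. The median of these 10 genes was thus lower than that of the other adrenal markers, -0.12. Single genes overlapped, with Lef1 of the zone at -0.05 and the lowest of the 12 cortex markers at -0.48. The list was picked for its low median before the random lists were drawn, so the percentile is no independent test of dilution. Less of the outer gland in the sample stays open, since the capsule and fibroblast list had a median of 0.38 with a spread of 0.44 between members that other tissues also express. A shift of the whole zone program stays open too, since a second list had a median of 0.11 with 5 genes higher and 4 lower and a spread of 0.57. That median is the log2 ratio of Kcnj5, a gene with 13 counts in replicate 1 and 14 in replicate 2. Its counting interval ran from 0.470-fold to 2.49-fold. Both medians lay past the limits at which these explanations were to be rejected. They stay open only by the later requirement to clear a limit by more than the spread of the members. The limit for the second zone list had been written before its values were looked up. The explanations left open cannot be told apart with these lists, and with 1 group the design gives no biological contrast to test them against.

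Short transcripts were nearly absent from the second transcript table. Genes shorter than the mean fragment of 332 nucleotides that the effective lengths of that table imply had a median log2 count ratio to the gene table of -11.12 (102 genes). Reads shared between identical copies are argued against as the whole cause, since 77 short genes with a sequence found once had a median of -9.98. A minimum fragment length of the second quantification could produce the loss but stays open, because genes 1 to 1.5 times as long as the mean fragment also had a low median of -3.45, which the simple form of that explanation had excluded. No biological explanation was tested, since both tables come from the same libraries.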

How the results depend on the processing

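The scaling without mitochondrial rRNA, the second table for the coefficient of variation and the chi-square index, the count minimum of 100 for that index and the rescaled comparisons of the quantifications were chosen only after the data were seen; the lists, the rule for named genes and all other alternatives were chosen before the data were examined. Genes more than 2-fold apart numbered 551 to 591 over the scalings and the second table, 1405 with a count minimum of 10 (1179 higher, 226 lower) and 145 with 1000 (143 higher, 2 lower), where the minimum itself sets how many genes are compared. Detected genes ranged from 11921 to 17554, the coefficient of variation from 19.04% to 21.1%, and the chi-square index from 55.3 to 78.6. Lists standing apart numbered 16 to 21. The log2 ratio of the zona glomerulosa list stayed between -0.53 and -0.44 and that of the liver list between 1.56 and 1.68 under every alternative run for them. The value of 1.56 is the mean of the liver list in place of its median. For the values below the cause was not tested unless the setting itself gives it. The replicate r was 0.988 with a pseudocount of 0.1 and 0.981 over detected genes, and the r between quantifications 0.944 with a pseudocount of 0.1. Rescaling TPM over nuclear coding genes, which raises every coding gene, put the cortex level at 9.59 and the chromaffin level at 5.94 on the log2 scale, and the second table at 8.80 and 4.71. Cortex over medulla was 3.59 with a pseudocount of 1, 4.09 in the second table and 2.83 with the mean of the lists, and Star over Th was 3.22 in the second table. As shares of TPM, spike-ins took 1.19%, the mitochondrial genome 21.2%, nuclear coding genes 33.3% and misc_RNA 28.6%. Genes more than 2-fold apart between the quantifications numbered 1583 at a minimum of 10 TPM and 2136.5 after rescaling, and 700.5 with both. The mitochondrial genome list reversed to -0.00170 under the library total, whose scaling includes those reads, and Gm45837 reversed to 0.0707 in the second table. Gm14440 and 1700047I17Rik2 had too few counts there for a value. Leaving out a library leaves no ratio between the libraries; where a value exists for one, the cortex over medulla value ran from 3.62 to 3.68. Depth limits genes near 3 counts, such as the pancreas markers.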

Other observations

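Apart from the comparison of the highest gene of the PPARA target list with the liver list, which was added after the values were seen, no test here was chosen only after its own result was seen: the bone and cartilage list and the PPARA target list were written after the replicates had been compared and before the values of their members were looked up.

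Members of the circadian clock list lay apart in both directions between the replicates while the list's median did not. In replicate 2 Per1 was at 1.42-fold, Per2 at 1.34-fold and Per3 at 1.69-fold, while Arntl was at 0.705-fold and Nr1d1 at 0.559-fold. Among imprinted genes, H19 was at 365 TPM in replicate 1 and 932 TPM in replicate 2, Igf2 at 211 and 457 TPM, and Peg10 at 145 and 94.1 TPM, while Dlk1, at 192 and 156 TPM, and Meg3, at 208 and 160 TPM, were closer. The lowest ratio of that list was that of Phlda2, on 7 and 2 counts. Per2, Per3, Arntl, Nr1d1, Peg10, Phlda2 and Dlk1 were chosen after their values were seen.

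Other genes chosen after their values were seen were higher in replicate 2 and encode fetal liver, elastic fibre, bone or fatty acid proteins. Afp, alpha-fetoprotein, was 6.50-fold higher, Igfbp2 6.10-fold, Eln, elastin, 5.81-fold, Cyp4a14 4.97-fold, Spp1, osteopontin, 12.2-fold, Acan, the cartilage proteoglycan, 11.7-fold and Ctsk, the osteoclast protease, 4.76-fold. Of the follow-up lists, the second skeletal muscle list had a median log2 ratio of 1.28 with 12 of 12 genes higher, and the second brown fat list had 0.43 with 6 higher and 4 lower. Both stood apart from random lists as higher in replicate 2, at percentiles 100 and 99.98. In the brown fat list Kcnk3, at a mean of 212 TPM, was at 0.804-fold and Cpt1b, at 180 TPM, at 0.982-fold. Of its higher genes, Cox6a2, at 5.77 TPM, was at 2.60-fold and Fabp3, at 30.9 TPM, at 1.48-fold.

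The bone genes among the largest differences gave the hypothesis that the sample of replicate 2 held bone and cartilage RNA. A second list of 16 genes, none of them seen before, had 15 with enough counts, all of them higher in replicate 2, with a median log2 ratio of 2.01, or 1.87 with the 2 genes at 0 counts in replicate 1 set at their bound. This is consistent with bone and cartilage RNA in that sample, at a low level: the most abundant genes of the list were Acp5 at 7.86 and 24.7 TPM, Alpl at 4.30 and 6.53 TPM and Bglap2 at 0.320 and 7.97 TPM in replicates 1 and 2. Alpl, Acp5 and Runx2 are also expressed in other tissues, and Hapln1 was at 1.04-fold. Bglap2 lies close to Bglap on chromosome 3, and Bglap was among the genes that raised the hypothesis. Both have fractional expected counts, so some of their reads may be shared and Bglap2 is not independent of Bglap. The log2 ratios of the members had a spread of 1.92, and the requirement to clear a limit by the spread was not applied to this list.

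Fgf21, Cyp4a10 and Cyp4a14 are targets of PPARA, a receptor active in fasting liver, which gave the hypothesis that the liver RNA of replicate 2 carried more PPARA target expression than liver admixture alone gives. The PPARA target list had a median log2 ratio of 0.83, with 7 genes higher and 3 lower, which is -0.86 relative to the second liver list, and its highest gene exceeded that list's median by 0.07. Some of its genes did not follow the liver list, such as Ehhadh at 52.1 and 45.2 TPM, which lowers the median, but no gene of the list reached the excess of 0.2 below which the hypothesis was to be rejected. By its written limit the test went against the hypothesis for the genes of this list. It cannot decide the hypothesis, since members that did not follow the liver list lower the median under either outcome. The list also leaves out the 3 genes that raised the hypothesis. Fgf21 at 38.4-fold, Cyp4a10 at 18.4-fold and Cyp4a14 at 4.97-fold all lie above the median of the second liver list, 3.23-fold. The single genes named from the bone and cartilage list and from the PPARA target list were chosen after their values were seen.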
